A study of Homo sapiens with 140 samples.

How the data were processed

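The deposited table holds one z-score per probe and array, the unit called score here: per the values themselves, each of the 140 arrays has a mean within 0.000418 of 0 and an SD of 1.00 over 9600 probes, rounded by the authors to 2 decimals. What the authors did before this scaling (array type, label, background correction, log transform and its base) is not given in the sources used here. The values run from -7.34 to 5.56. Differences between arrays are therefore in SDs of an array, they carry no fold change, and an array-wide change in RNA amount or in the spread of signals is removed by the scaling. Because each array has its own SD, a z-score also moves when the spread of the other probes moves. The interquartile range was 1.39 to 1.49 in total RNA arrays and 0.693 to 1.31 in fraction arrays, and array medians lay between -0.04 and 0.02 and between -0.24 and 0.01. There were no missing values and no 2 arrays held identical values. The SD of the difference between 2 arrays of one group ranged from 0.264 to 0.762.

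Groups and repeats were taken from the labels: total RNA or fraction number, untreated or 3 h, 6 h or 12 h after UVC, and biological repeat 1 to 3. The UVC dose and the collection of the gradients are not given in the sources used here. Fraction 1 of untreated replicate 3, fraction 5 of 3 h replicate 3, and fractions 4 and 5 of 12 h replicate 3 were not analysed here. Probes were named through the platform annotation supplied with the data: 8496 probes have 1 gene symbol, 21 have several and were left unnamed, and 1083 are not listed. Symbols were checked by gene identifier against the RefSeq gene table of GRCh38.p14, which changed 0 of them and did not hold 3 of the identifiers. The named probes cover 6284 genes. TIAL1 has no probe with a single symbol.

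Total RNA was tested in 1 model over the 12 arrays with 4 groups, with lmFit and eBayes of limma 3.58.1 in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment over 9600 probes and a threshold of 0.05. For the gradients, a position score was computed per probe and gradient as the mean z-score over fractions 6 to 11 minus the mean over fractions 2 and 3, the fractions listed for all 12 gradients, and the 12 scores were tested in the same way. The gradient is the replicate. The contrasts were each time against untreated cells, 12 h against 3 h, an F-test over the 3 times, and the mean score of untreated gradients against 0. Adjusted p values in the text come from these limma models or, for gene lists, from camera. Camera ran on 21 lists (pathways, complexes and markers of other cell types) with 1 probe per gene, the one with the highest mean, and with a preset correlation of 0.01; the estimated correlation and fry were alternatives. Single sets of genes outside the 21 lists were tested with camera without adjustment, and beside each p stands the exact permutation p, the share of all splits of the samples (or sign changes of the untreated gradients) with a camera p as small. P values were adjusted over the lists of a contrast. Called means past the threshold.

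The design, the lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule names MYC and TIAL1 and, per comparison and direction, up to 8 genes with the largest change among those past the threshold whose 3 treated values all lie on one side of the 3 untreated values. Where fewer than 3 passed, it names the 3 with the smallest p, and for each called list the 4 members with the smallest p in its direction. Of a gene with several probes the probe with the highest mean was used. Genes outside the rule are marked in the text. A test against gene and coding length was planned and not run: the reference table holds no coding lengths, and with no genome build named for the arrays it was used for names only.

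The models were tested on simulated data over 9600 probes with the spread of these samples and 200 probes shifted. For total RNA at 12 h they recovered 25.4%, 79.1% and 95.5% of shifts of 0.25, 0.5 and 1, with 6 unchanged probes called. For the position shift at 12 h they recovered 0%, 32.8% and 89.4%, with 7 unchanged probes called. A list of 50 genes shifted by 0.15 was recovered in both, and 0 of 20 unshifted lists were called. The simulated noise was drawn independently per probe and the lists held random genes. The simulation therefore does not test how the list calls behave when list members are correlated. The alternatives were median centring, quantile normalization, leaving out the dimmest 25% or 50% of probes, averaging probes per gene, eBayes with trend and robust, array weights, leaving out each sample, the replicate number as a block, and other definitions of the position score. Each of the 12 total RNA arrays and 105 of the 128 fraction arrays have a shared low value, which is the most frequent value of the array where at least 2 times as many probes hold it as the next and it lies below the median. What put these probes there is not given in the sources used here. Leaving out the probes at or below it, on any array or on at least 25% of them, was an alternative chosen after seeing the data. A first form of this rule took the most frequent value of every array; it was replaced after its counts had been seen, because on the other 23 fraction arrays that value is not a distinct low one. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.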

Results

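RKO cells, a human colon carcinoma line, were exposed to ultraviolet C light (UVC) and compared with untreated cells at 3 h, 6 h and 12 h, with 3 biological repeats per condition. Total RNA was hybridised to 12 arrays, and RNA from up to 11 numbered fractions of each of 12 polysome gradients to 128 more. The title of the series names TIAR, an RNA-binding protein that holds back translation, and the transcription factor c-Myc. The comparisons therefore ask which mRNAs changed in abundance after UVC, and which changed their place along the gradient. Values are z-scores within each array over 9600 probes, so every change below is in SDs of an array and is not a fold change. The deposited scale keeps no signal over background, so precision rests on the number of arrays. On each total RNA array, 779 to 1180 probes hold 1 identical low value, between -1.14 and -1.02, and 2482 probes lie at or below it on at least 1 of these arrays. The size of a change and its rank are uncertain there, and genes concerned are marked. The 12 total RNA arrays correlated with each other at 0.928 to 0.965, and a fraction array correlated on average at 0.754 to 0.928 with the other arrays of its fraction.

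At 3 h, MYC, the gene of c-Myc, had a total RNA value of 0.61 ± 0.26 against 0.95 ± 0.09 in untreated cells (SD, n = 3). That change of -0.34 ± 0.19 (SE) did not pass the test (adjusted p = 0.98). No probe passed at this time. The smallest adjusted p values, both 0.0701, belonged to SERTAD1, a regulator of cyclin-dependent kinase activity, with a change of 0.35 ± 0.04, and to JSRP1, with -0.62 ± 0.08. The other genes with the smallest p were USP33, a deubiquitinase (1.14 ± 0.21), RGS2, a regulator of G-protein signalling (0.25 ± 0.06), ID3, an inhibitor of helix-loop-helix transcription factors (-0.35 ± 0.06), and GEMIN4, a member of the SMN complex (-0.24 ± 0.04), and none of them passed. Of the 6 arrays compared, JSRP1 was at or below the shared low value on 6, USP33 on 4 and RGS2 on 2. None of the 21 gene lists was called. The limma test gave 0 of 9600 probes past adjusted p 0.05 and 415 at an unadjusted p under 0.05, where 480 are expected by chance. Weighting the arrays by their quality raised the count to 23. Without the probes at the shared low value on any total RNA array, 1 probe passed, SERTAD1 (adjusted p = 0.0497).

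At 6 h, 19 probes had risen and 82 had fallen in total RNA past the threshold. LSM10, a component of the particle that processes histone mRNA ends, fell from 0.40 ± 0.03 to -0.14 ± 0.06, and TEAD4, a transcription factor of the Hippo pathway, from 0.55 ± 0.05 to 0.06 ± 0.03 (SD, n = 3; adjusted p = 0.00395 for both). SERTAD1 rose from 0.37 ± 0.05 to 0.75 ± 0.05 (adjusted p = 0.00754). CXCL5, a chemokine that attracts neutrophils, rose by 0.38 ± 0.06 (SE), and PTBP1, a splicing regulator, by 0.30 ± 0.04. The 2 other probes of PTBP1 gave -0.14 and 0.20 without passing. MYC stood at 0.47 ± 0.41, a change of -0.48 ± 0.19 (SE) that did not pass (adjusted p = 0.263), and its dimmer probe gave -0.14 ± 0.07.

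The other large increases at 6 h were in PKD1P1, a pseudogene (0.59 ± 0.11), RPL21, a ribosomal protein gene (0.30 ± 0.06), MYBL2, a transcription factor of cell cycle genes (0.28 ± 0.05), ERCC2, a helicase of nucleotide excision repair (0.27 ± 0.05), and SFN, a target of p53 (0.26 ± 0.04). The 2 other probes of SFN gave -0.25 and -0.09 without passing, and the mean over its probes had the opposite sign. Decreases were found in DENND2D (-0.62 ± 0.09), in BYSL, a ribosome biogenesis factor (-0.49 ± 0.07), in NAA60, an acetyltransferase (-0.49 ± 0.08), and in LRRC14 (-0.48 ± 0.07). SNAPC1, which acts in small nuclear RNA transcription, fell by 0.45 ± 0.08, and GTF3C5, a subunit of a polymerase III factor, by 0.45 ± 0.05, while their other probes gave 0.18 and -0.05 without passing. PLK1, a mitotic kinase singled out after its values were seen, fell on all 3 of its probes, by 0.39 ± 0.07, 0.57 ± 0.09 and 0.71 ± 0.11 (adjusted p = 0.0319, 0.0187 and 0.018).

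Of the 58 measured ribosomal protein genes, 47 lay above 0 at 6 h with a median change of 0.14, and of 56 oxidative phosphorylation genes 46 did, with a median of 0.14. Both lists were called upward by camera with a preset correlation (adjusted p = 1.81e-07 and 1.20e-06). Neither call held with an estimated correlation (adjusted p = 0.308 for both). Among ribosomal protein genes 1 passed over all probes and 11 passed adjusted over the list alone, and for oxidative phosphorylation both counts were 0. RPL41 changed by 0.18 ± 0.04, RPL35A by 0.25 ± 0.06 and RPS12 by 0.37 ± 0.10, none past the threshold over all probes. NDUFB1 gave 0.18 ± 0.04, ATP5PO 0.41 ± 0.11, NDUFS5 0.30 ± 0.08 and NDUFA1 0.18 ± 0.05, likewise short of it. Leaving out any 1 of the 6 arrays left between 4 and 34 probes past the threshold in place of 101, fewest without UVC 6 h replicate 2. Array weights gave 251 higher and 277 lower.

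At 12 h, 131 probes had risen and 256 had fallen past the threshold. MED27, a Mediator subunit, fell from 0.39 ± 0.05 to -0.26 ± 0.10, and MCRS1 from 0.70 ± 0.03 to 0.18 ± 0.10 (SD, n = 3; adjusted p = 0.00189 for both). CXCL5 rose from 1.32 ± 0.10 to 1.93 ± 0.05 (adjusted p = 0.00228). The histone genes H4C5 and H4C9 fell by 0.68 ± 0.13 and 0.65 ± 0.11 (SE). MYC stood at 0.64 ± 0.11, a change of -0.31 ± 0.19 that did not pass (adjusted p = 0.42).

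**Figure D1:**
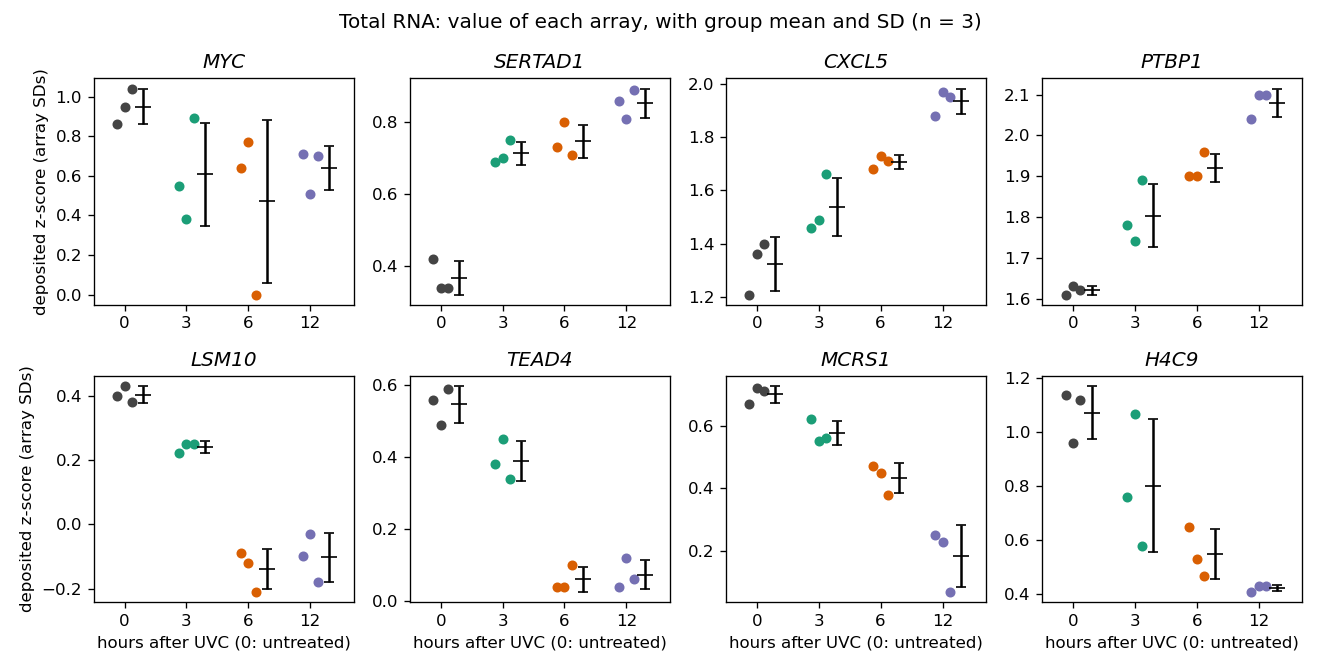
Total RNA values of 8 genes on each of the 12 arrays, as deposited z-scores in SDs of an array (vertical axis), against hours after UVC (horizontal axis, 0 for untreated cells). Points are arrays and the black bars the mean and SD of 3 arrays. MYC spread over 0.47 ± 0.41 at 6 h, while SERTAD1, CXCL5 and PTBP1 lay higher and LSM10, TEAD4, MCRS1 and H4C9 lower than in untreated cells at 12 h.

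The other large increases at 12 h were in POLR3F, an RNA polymerase III subunit (0.64 ± 0.14), PKD1P1 (0.61 ± 0.11), ANKRD36BP1, a pseudogene (0.58 ± 0.09), and EDEM3, which acts in the breakdown of glycoproteins of the endoplasmic reticulum (0.57 ± 0.13). SOX9, a developmental transcription factor, rose by 0.52 ± 0.10 and CFAP300 by 0.52 ± 0.08. Decreases were found in PKNOX1, a homeobox transcription factor (-1.07 ± 0.21), ZBED10P, a pseudogene (-1.07 ± 0.21), and CNKSR1, a scaffold of Ras signalling (-0.67 ± 0.12). The other probe of CNKSR1 gave -0.02 ± 0.04, as a probe held at the shared low value does, so it may carry no measurement. Of the 6 arrays compared, POLR3F, ANKRD36BP1 and ZBED10P were at or below the shared low value on 3, and EDEM3 and PKNOX1 on 2, so the sizes and ranks of these 5 are uncertain. USP33 (0.96 ± 0.21) and BBOX1, an enzyme of carnitine synthesis (-0.93 ± 0.15), also passed, but both lay at or below that value on all 6 arrays, so no change in abundance, in either direction, is read from them. Of the 387 probes past the threshold, 17 lay at or below it on at least 1 of the total RNA arrays. The following genes were singled out after their values were seen. KRT18, a keratin of simple epithelia with 6 probes, fell on 5 of them by 0.40 to 0.49, and the sixth gave -0.18 ± 0.07 (adjusted p = 0.193). CDKN1A, the cell cycle inhibitor p21 and a target of p53, rose by 0.42 ± 0.05 and 0.32 ± 0.05 on 2 of its 3 probes (adjusted p = 0.00425 and 0.0106), and the other gave 0.21 ± 0.07 (adjusted p = 0.107).

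Ribosomal protein and oxidative phosphorylation genes were again the lists called upward at 12 h (adjusted p = 3.87e-08 and 0.000191), with medians of 0.15 and 0.09 and with 49 and 45 members above 0. With an estimated correlation neither call held (adjusted p = 0.243 and 0.299). RPL21, RPL41 and RPL23A rose by 0.31 ± 0.06, 0.21 ± 0.04 and 0.28 ± 0.06, while RPS12 gave 0.38 ± 0.10, UQCRQ 0.30 ± 0.08, NDUFS5 0.30 ± 0.08, ATP5F1E 0.39 ± 0.11 and NDUFA1 0.18 ± 0.05 without passing. Adjusted over the list alone, 13 ribosomal protein genes and 0 oxidative phosphorylation genes passed.

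The genes in this paragraph, apart from CDKN1A, are called members of the fixed lists, and all were named outside the rule after their values were seen. Of 23 targets of p53, SFN, TRIAP1 and TP53I3 rose at 12 h, by 0.34 ± 0.04, 0.32 ± 0.06 and 0.30 ± 0.06. The value of SFN is that of its brightest probe. The 2 other probes of SFN had given -0.25 and -0.09 at 6 h without passing, and their values at 12 h are not given here. CDKN1A stands in this list by its brightest probe, which did not pass (0.21 ± 0.07, limma adjusted p = 0.107). Of the list, 5 genes rose adjusted over the list alone and none fell, and the list was not called (adjusted p = 0.109). Of 30 genes of DNA replication and G1/S, POLD2, POLA2 and GINS2 fell, by 0.23 ± 0.03, 0.17 ± 0.04 and 0.28 ± 0.06, 4 fell adjusted over the list alone, and the list was not called (adjusted p = 0.122). Among 20 genes of nucleotide excision repair, ERCC2 rose by 0.40 ± 0.05, while ERCC3 fell by 0.28 ± 0.06 and RPA1 by 0.21 ± 0.04. Among 18 genes for AU-rich element and stress granule proteins, the class to which TIAR belongs, PTBP1 rose by 0.46 ± 0.04 (its other probes gave -0.08 and 0.15) and PCBP2 and HNRNPD fell by 0.33 ± 0.05 and 0.29 ± 0.06. ATF3, a stress-induced transcription factor, fell by 0.39 ± 0.07, the only called member of 22 immediate early genes. Of 13 markers of other cell types 1 rose and none fell (2 rose adjusted over the list alone), and that list was not called (adjusted p = 0.838). Leaving out 1 of the 6 arrays gave 94 to 374 probes in place of 387, fewest without UVC 12 h replicate 3, and array weights gave 1133, of which 536 were higher and 597 lower. Median centring moved the division into 215 higher and 255 lower.

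Both later times were measured against the same 3 untreated arrays. Of the 19 probes higher at 6 h, 16 were also higher at 12 h, and of the 82 lower probes 51 were also lower. Independent lists of these sizes would share 0.259 and 2.19 probes. In 100 simulations of unchanged groups against the same controls 0 were shared, which says nothing about the overlap, since they called only 0.05 probes on average at 12 h. The changes at the 2 times correlated across probes at 0.639, against 0.498 in the simulations, with a covariance of 0.026 against 0.0115. The 3 untreated arrays are too few to be split between the times, so part of the excess of the shared probes over independent lists may come from sharing them. The simulated covariance holds that sharing for noise drawn independently per probe, and the observed one is larger. A deviation of the untreated arrays common to many probes was not simulated, so the larger value does not tell it from an effect of UVC.

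Compared directly with 3 h, 12 h had 40 probes higher and 95 lower in total RNA past the threshold. MED27 and MCRS1 were lower by this test, with differences of -0.56 ± 0.07 and -0.39 ± 0.05 (SE; adjusted p = 0.0118 and 0.0173, 3 arrays each), and CXCL5 was higher by 0.40 ± 0.06 (adjusted p = 0.0221). Over the 3 times together, 201 probes differed from untreated cells by the F-test. The division between higher and lower depended on the setting. Quantile normalization gave 169 higher and 182 lower for 12 h against 3 h, array weights 835 and 606, and leaving out the probes at the shared low value on any total RNA array 116 and 160. Leaving out 1 array gave 4 to 99 in all, with 50 higher and 49 lower without UVC 3 h replicate 3. For the F-test, leaving out 1 array gave 43 to 212 probes and array weights 1735.

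In untreated cells, mRNAs differed widely in their place along the gradient. The position score is the mean over fractions 6 to 11 minus the mean over fractions 2 and 3, and the labels do not say which end of the numbering is the heavy one. PHB1, a mitochondrial scaffold protein, scored 1.50 ± 0.10 and TXN, the redox protein thioredoxin, 1.34 ± 0.23, while RMND5A, part of a ubiquitin ligase, scored -1.63 ± 0.29 and GCAT, an enzyme of threonine breakdown, -1.30 ± 0.04 (SD, n = 3 gradients). MYC scored 0.37 ± 0.11 (adjusted p = 0.0131), and its value was highest in fraction 10, at 0.90 ± 0.28. The other MYC probe scored 0.06 ± 0.08 (SE) without passing (adjusted p = 0.702). RMND5A was at a shared low value on 7 of the 24 fraction arrays behind its score. In all, 873 of the 9600 probes were called above 0 and 1001 were called below.

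Oxidative phosphorylation genes scored high, with a median of 0.28 and 52 of 56 genes above 0 (camera adjusted p = 1.93e-10, but 0.0705 with an estimated correlation), and NDUFB4, COX7B, NDUFS5 and COX6C scored 1.05 ± 0.10, 0.83 ± 0.12, 0.71 ± 0.10 and 0.69 ± 0.11. Proteasome genes scored high as well, with a median of 0.32 and 21 of 28 above 0 (adjusted p = 1.11e-05, but 0.18 with an estimated correlation); PSMB7 reached 1.17 ± 0.09, PSMA7 1.11 ± 0.22, PSMC1 1.10 ± 0.10, PSMA3 1.05 ± 0.28 and PSMB3 0.67 ± 0.09. Ribosomal protein genes scored low, with a median of -0.14 and 41 of 58 below 0 (adjusted p = 0.000113, but 0.393 with an estimated correlation), among them RPLP1 at -1.01 ± 0.18, RPS28 at -0.86 ± 0.18, RPS20 at -0.75 ± 0.05 and RPL39 at -0.70 ± 0.04. PSMA3 was at or below a shared low value on 3 of the 24 fraction arrays behind its score. The ribosomal protein list was not lower in every fraction of the high end. Its median was highest in fraction 6 (2.47 ± 0.22). In fraction 8 (2.30 ± 0.17) it was close to fractions 2 and 3 (2.31 ± 0.06 and 2.30 ± 0.09). Position scores were not compared with random lists matched on brightness. None of the 3 calls held with the estimated correlation. Over all probes, 26 oxidative phosphorylation and 14 proteasome genes passed upward and 20 ribosomal protein genes downward, and adjusted over the list alone 28, 14 and 22 did.

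**Figure D2:**
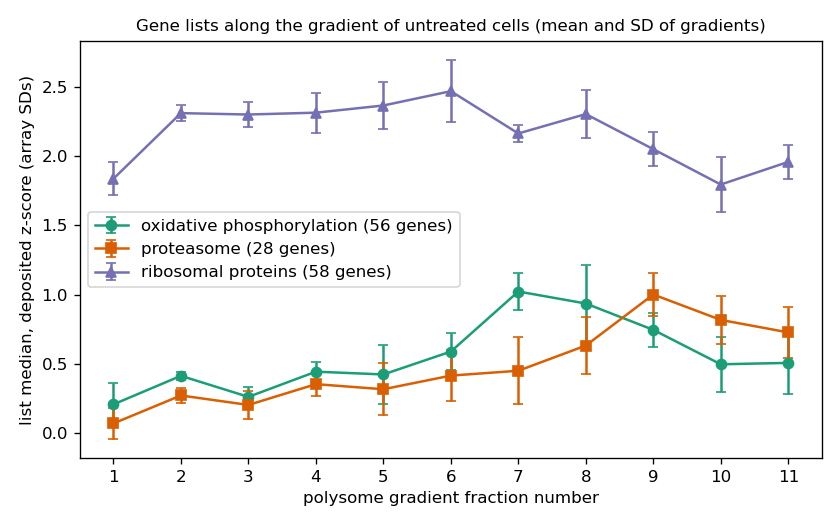
Median z-score of 3 gene lists, in SDs of an array (vertical axis), in each of the 11 gradient fractions of untreated cells (horizontal axis). Points and bars are the mean and SD of 3 gradients, or of 2 in fraction 1. Oxidative phosphorylation genes were highest in fraction 7 (1.02 ± 0.14) and proteasome genes in fraction 9 (1.00 ± 0.15). Ribosomal protein genes were highest in fraction 6 (2.47 ± 0.22) and lowest in fraction 10 (1.79 ± 0.20).

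Other genes with a high score were CEP95, a centrosomal protein (1.41 ± 0.28), COPS8, a COP9 signalosome subunit (1.25 ± 0.14), and SATB1, a chromatin organiser (1.13 ± 0.25). COPS8 and SATB1 were each at or below a shared low value on 3 of the 24 fraction arrays behind their scores. Low scores were also found for LNROP (-1.32 ± 0.12), the protease gene CTSK (-1.26 ± 0.10), FMO9P, a pseudogene (-1.24 ± 0.13), AEBP2, a cofactor of Polycomb repression (-1.24 ± 0.01), MIEF2, a mitochondrial fission factor (-1.23 ± 0.11), and CREB3L1, a membrane-bound transcription factor (-1.23 ± 0.17), whose other probe gave -0.08 without passing. Setting fractions 1 to 3 as the low end, with 2 untreated gradients, gave 591 probes called above and 199 called below 0. Without the first of the 3 untreated gradients, 1132 probes passed in place of 1874.

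After UVC, no probe changed its position score past the threshold at 3 h, 6 h or 12 h. MYC scored 0.28 ± 0.14 at 3 h, 0.23 ± 0.20 at 6 h and 0.26 ± 0.15 at 12 h (SD, n = 3), which are differences of -0.09 ± 0.13, -0.14 ± 0.13 and -0.11 ± 0.13 (SE) from untreated cells (adjusted p = 0.996, 1.00 and 0.954). The direction at 3 h turned with array weights (0.011), and at 12 h with the mean over both MYC probes (0.030). TIAL1, the gene of TIAR, has no probe of its own in the annotation used and is not analysed here.

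**Figure D3:**
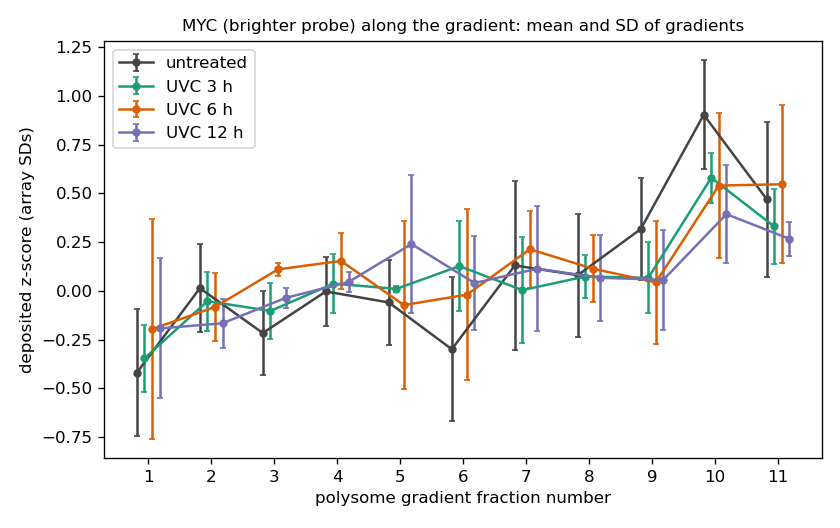
MYC along the gradient, from its brighter probe, as deposited z-scores in SDs of an array (vertical axis) by fraction number (horizontal axis; points of the 4 conditions are set slightly apart). Points and bars are the mean and SD of 3 gradients, or of 2 where a fraction was not analysed here. In fraction 10, singled out as the one with the highest value in untreated cells, the values were 0.90 ± 0.28 in untreated cells, 0.58 ± 0.13 at 3 h, 0.54 ± 0.37 at 6 h and 0.39 ± 0.25 at 12 h. In fraction 11 they were 0.47 ± 0.40, 0.33 ± 0.19, 0.55 ± 0.41 and 0.27 ± 0.09.

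The genes with the smallest p at 3 h were TMEM126A (0.41 ± 0.11), NTF4 (0.37 ± 0.09) and KIF1B (0.36 ± 0.09) upward and GPR137B (-1.89 ± 0.46), PLAGL2 (-0.82 ± 0.15) and SMAD1 (-0.78 ± 0.19) downward, with adjusted p = 0.996 for each. At 6 h they were FXR2, a relative of the fragile X protein (1.08 ± 0.27), LIMD2 (0.59 ± 0.13) and CHN1 (0.48 ± 0.08), and WDR24 (-0.69 ± 0.16), PLAGL2 (-0.60 ± 0.15) and MFF (-0.35 ± 0.09), with a smallest adjusted p of 0.714. At 12 h they were TCTN3 (0.58 ± 0.12), AKAP1 (0.47 ± 0.12) and PXMP2 (0.41 ± 0.10), and WDR24 (-0.86 ± 0.16), CFAP300 (-0.50 ± 0.09) and SH3BP5 (-0.40 ± 0.09), with a smallest adjusted p of 0.723. Several lay at a shared low value on many of the 48 fraction arrays compared: GPR137B on 36 and PLAGL2 on 19 at 3 h, WDR24 on 34, FXR2 on 31, PLAGL2 on 25 and LIMD2 on 13 at 6 h, and WDR24 on 35, TCTN3 on 17, AKAP1 on 15 and PXMP2 on 12 at 12 h. CDKN1A, singled out after its values were seen, gave 0.45 ± 0.11, 0.28 ± 0.09 and 0.09 ± 0.08 on its 3 probes at 12 h, and none passed. Unadjusted p values under 0.05 numbered 331, 320 and 492 at the 3 times, against 480 expected by chance. The limma F-test over the times gave 0 probes with 280 at an unadjusted p under 0.05, and 12 h against 3 h gave 0 with 371.

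Of the 21 gene lists, proteasome genes alone were called for a shift, downward at 12 h, with a median of -0.09 and 19 of 28 genes below 0 (camera adjusted p = 0.0255). With an estimated correlation the list was not called (adjusted p = 0.84), nor without the probes at a shared low value on any fraction array used (adjusted p = 0.39). PSMA3 went from 1.05 ± 0.28 to 0.48 ± 0.03, PSMB7 from 1.17 ± 0.09 to 0.77 ± 0.11, PSMC1 from 1.10 ± 0.10 to 0.84 ± 0.06 and PSMA4 from 0.51 ± 0.03 to 0.20 ± 0.07 (SD, n = 3), none past the threshold over all probes, and 2 genes passed adjusted over the list alone. PSMA3 and PSMA4 lay at a shared low value on 6 and 8 of the 48 arrays compared. Without single gradients the adjusted p ranged from 0.00334 to 0.199. The call was lost without untreated replicate 1 (0.199) or 2 (0.159), and without UVC 12 h replicate 1 (0.0611) or 3 (0.18).

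Changes in abundance and in position were compared across probes, which are not independent replicates. The Spearman correlation was 0.07 at 3 h, -0.10 at 6 h and 0.02 at 12 h, and among single repeats it ranged from -0.08 to 0.01, from -0.13 to 0.07 and from -0.08 to 0.10. The value at 3 h lies outside the range of its repeats. The probes that had risen in total RNA by 12 h had a median position change of -0.06, and those that had fallen one of -0.10. At 6 h these medians were -0.04 and -0.06.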

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

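The tests of the ribosomal protein and oxidative phosphorylation lists against array brightness and against the untreated arrays were fixed after the list calls had been seen and before their own results were, and the estimated correlation was an alternative for the list tests fixed before the data were examined. Its use for 12 h against 3 h and the look at the shared low value came after the results were seen. Groups of 3 are too small for a test of single outlying samples. What stands here are therefore effects in total RNA that differed between 3 h and 12 h by the test of the difference itself. Single genes were looked for only among those named for total RNA at 12 h against untreated cells. That selection and this test share the 12 h arrays, so the sizes of their differences may be overstated.

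MED27 changed by -0.09 at 3 h and by -0.65 at 12 h, a difference of -0.56 ± 0.07 (SE, limma adjusted p = 0.0118), and MCRS1 by -0.12 and -0.52, a difference of -0.39 ± 0.05 (adjusted p = 0.0173). CXCL5 changed by 0.21 and 0.61, a difference of 0.40 ± 0.06 (adjusted p = 0.0221). ANKRD36BP1 and CFAP300 were higher at 12 h than at 3 h by 0.48 ± 0.09 and 0.43 ± 0.08 (adjusted p = 0.0291 and 0.0339). ZBED10P and CNKSR1 were lower, with differences of -1.17 ± 0.21 and -0.59 ± 0.12 (adjusted p = 0.0291 and 0.0446). Of the 6 arrays of this comparison, ANKRD36BP1 lay at or below the shared low value on 2, both of 3 h, and ZBED10P on 3, all of 12 h, so the size of their difference is uncertain. The targets of p53 as a list were also higher at 12 h than at 3 h, with a median difference of 0.10 (camera adjusted p = 0.0107, but 0.219 with an estimated correlation), while at 12 h against untreated cells the list was not called (0.109).

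The ribosomal protein list differed between 12 h and 3 h with a median difference of 0.16 (camera adjusted p = 1.11e-08), and the oxidative phosphorylation list with one of 0.078 (adjusted p = 0.00347). With an estimated correlation these were 0.223 and 0.524. The untreated arrays do not enter that comparison, which argues against a shared offset of them only as far as the preset correlation holds. Scaling that acts by brightness is argued against as well: each of the 4 list medians at 6 h and 12 h lay at the 100th percentile (100%) of 10000 random lists matched on mean value, and the matched medians were -0.06 and -0.04 for the ribosomal protein list. Correlation between the members stays open, since the lowest of the 4 adjusted p values was 0.243 once it was estimated, and a handful of arrays that differ in RNA quality may move such a list together. A response of these genes to UVC stays open as a biological explanation. Because z-scores are relative to the other probes of an array, a rise of these genes cannot be told from a fall of others.

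The 6 arrays of a comparison of 3 with 3 make 10 splits, too few for a share under 0.05. For total RNA no other split reached the real counts: 101 probes at 6 h against at most 1 elsewhere, 387 at 12 h against 0, and 135 for 12 h against 3 h against at most 2, each reached by 1 split, the real one. At 3 h all 10 splits gave at least the real count of 0, as they must, with up to 7. For gene lists, 5 of the 10 splits at 6 h and 4 of the 10 at 12 h called at least the 2 lists of the real one, with up to 5 and 4 lists. List calls of this kind therefore arise in splits that mix the groups. A structure among the arrays and a correlation between list members above the preset one were not told apart as the source. The F-test over all times gave 201 probes. Of 100 splits of the 12 arrays, the real one included, only the real one gave as many, with at most 7 in the others. Chance is therefore an unlikely source of that count, but the splits cannot tell UVC from another difference between the groups.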

How the results depend on the processing

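With the 14 fraction arrays left out that correlated under 0.85 with their fraction, 0 probes passed for a position shift at any time. Those that enter the score were fraction 6 of untreated replicate 2, fraction 3 of 3 h replicate 3, and fractions 6, 8 and 10 of 6 h replicate 3. The others were of fractions 1 and 5, which the score does not use. The alternative without weak arrays was chosen after seeing the data, as were the list tests after quantile normalization and without single samples, the use of simulated recovery, and the settings on the shared low value. None of the other alternatives gave a position shift either, so the count of 0 held throughout; all 10 splits of each 3 against 3 comparison of gradients gave at least 0, with at most 0 at 3 h, 1 at 6 h, 0 at 12 h and 0 for 12 h against 3 h, and for the F-test all 100 did, with up to 22. A real count of 0 is reached by every split by construction, so these shares test nothing, while the 22 points to a structure of the gradients other than the conditions; same-numbered gradients that deviate together would be one. The spread of the gradients limits this: 32.8% of simulated shifts of 0.5 were recovered. The planned test against gene and coding length was not run. The correlations of total RNA with position were 0.07, -0.08 and 0.02 after quantile normalization and 0.07, -0.05 and 0.05 without the weak arrays.

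Total RNA counts depended on the setting; the cause was not tested, except that averaging probes leaves fewer tests and leaving out a sample fewer arrays. In the order 3 h, 6 h, 12 h, 12 h against 3 h and any time (main 0, 101, 387, 135 and 201), array weights gave 23, 528, 1133, 1441 and 1735. Quantile normalization gave 170, 599, 351 and 372 for the last 4. Without the dimmest 25% of probes there were 258 and 359 for the last 2, without the dimmest 50% 327 and 382 (and 1 at 3 h), and with trend and robust 249 and 327 (and 1 at 3 h). Without the probes at or below the shared low value on any array there were 1, 168, 583, 276 and 398, and without those on at least 25% of arrays 240 and 345 for the last 2. Probes averaged per gene gave 2, 55 and 256 at the 3 times. Without single samples the counts ranged over 0 to 3, 4 to 34, 94 to 374, 4 to 99 and 43 to 212. For the position in untreated cells (main 1874) they ranged over 1132 to 1396, with 1210 for averaged probes and 790 with fractions 1 to 3 as the low end. Leaving out probes at or below the shared low value on any array gave 1691, on at least 25% of them 1970. The first form of that rule, seen before it was replaced, gave 458 and 1962.

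Of the 8 list calls, 0 held with the correlation estimated per list: adjusted p = 0.308 for both lists at 6 h, 0.243 and 0.299 for ribosomal proteins and oxidative phosphorylation at 12 h, 0.84 for the proteasome shift, and 0.393, 0.0705 and 0.18 for ribosomal proteins, oxidative phosphorylation and proteasome in untreated cells. Fry called 22 lists in a direction and 49 mixed, and gave 0.667 and 0.208 for the proteasome shift, which ranged over 0.00334 to 0.199 without single gradients and was 0.39 without the probes at the shared low value on any array. The other 7 list calls held in every other setting run. For fry this means only a call against no change, whereas camera compares a list with the other genes.

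The labels do not say whether repeat numbers pair the samples, so the main tests and the simulated recovery disregard them. Same-numbered gradients still deviated together, which is seen in the data and not given by the design. Of 18 same-numbered pairs, 13 correlated above 0.1 in position score (-0.06 to 0.38) and 3 in total RNA (-0.15 to 0.17), with medians of 0.21 and 0.04 against -0.10 and -0.02 for different numbers, and 10 of 12 gradients and 6 of 12 arrays correlated best with their own number. The 6 pairs of number 1 ranged over 0.20 to 0.38 in position score, and the splits of the gradients disregard these numbers. With the replicate block, 0 probes passed for position, 74 at 6 h, 342 at 12 h, 105 for 12 h against 3 h and 104 for any time. The 5 list calls for which the block was run held, and it was not run for the 3 of untreated cells.

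Among named genes, 1627 values under alternatives stayed on their side of the threshold in the same direction, 141 fell short of it, 59 passed it, and 3 turned: SFN at 6 h with averaged probes (-0.024), MYC position at 12 h with averaged probes (0.030), and MYC position at 3 h with array weights (0.011).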

Other observations

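Histone genes as a set lay lower in total RNA at 3 h by camera, in a test chosen after its result had been seen. Of 14 genes of the replication-dependent histone clusters, without H4C5 and H4C9, 13 lay below 0 at 3 h with a median change of -0.10, for instance H2BC15 (-0.28 ± 0.07, SE), H1-2 (-0.26 ± 0.07), H2BC12 (-0.23 ± 0.07) and H2AC6 (-0.13 ± 0.04). None of these genes passed alone, and the set did by camera (p = 5.36e-09, and p = 0.0012 with an estimated correlation; exact permutation p = 0.1, the smallest that 10 splits allow). At 12 h the same 14 genes had a median of -0.02, and they were higher than at 3 h (camera p = 0.0214, or 0.0899 with an estimated correlation; exact permutation p = 0.1). One of the 14, H2BC4, lay at the shared low value on every total RNA array, so it holds no measurement. Of the other 13 genes, 12 lay below 0 at 3 h with a median of -0.11 (camera p = 2.17e-09, or 0.00223 with an estimated correlation; exact permutation p = 0.1). At 6 h the 14 genes had a median change of -0.07, with 9 below 0 and 5 above. The 4 measured H4 genes had changes of -0.44 to -0.06 at 3 h, none past the threshold. Their changes were -0.65 to -0.34 at 6 h and -0.68 to -0.30 at 12 h. Histone copies are close in sequence, so a probe can read several of them.

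Genes of mitochondrial ribosomal proteins also scored high along the gradient of untreated cells by camera (p = 4.60e-05), but not with an estimated correlation (0.136; exact permutation p = 0.25). Of 55 genes, 42 scored above 0 with a median of 0.12, 13 passed upward and 0 downward, with MRPS26 at 0.79 ± 0.12 (SE), MRPL20 at 0.77 ± 0.13 and MRPL22 at 0.71 ± 0.06.

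The tests of histone genes at 3 h, the look at the shared low value and all exact permutation tests were chosen after the result was seen. The others in this part were fixed after the named genes and lists had been seen and before their own results were. That H4C5 and H4C9 stand for all histone genes at 12 h was one hypothesis, and the other 14 did not show it at that time (camera p = 0.324, exact permutation p = 0.6). At 3 h the decrease of those 14 genes held by camera without each of the 6 arrays (highest p = 1.69e-05; exact permutation p of the set 0.1). This argues against a single array as its source only as far as the preset correlation holds. It also held after both other scalings (highest p = 7.66e-09; exact permutation p of the set 0.1), but these cannot decide on scaling. Median centring shifts all genes of an array alike, and camera compares the set with the other genes. Quantile normalization acted on arrays already alike in spread (interquartile range 1.39 to 1.49). Of the 10 splits of these 6 arrays only 1, the real one, gave a p as small, and the next was 0.0003; 10 splits are too few for a share under 0.05. A loss of histone mRNA when DNA replication is blocked by UVC damage may account for it, as a hypothesis that was not tested further.

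A further hypothesis was that genes of mitochondrial ribosomal proteins move with those of oxidative phosphorylation. Their place in untreated cells left this open (camera p = 4.60e-05, but 0.136 with an estimated correlation; exact permutation p = 0.25, the smallest that 3 gradients allow). Their total RNA at 12 h did not follow, with a median of -0.03 (camera p = 0.205, exact permutation p = 0.4). Another was that other keratins fall with KRT18 at 12 h. The 7 others did not show it (camera p = 0.86, exact permutation p = 0.9), and KRT8, the partner of KRT18 in filaments, gave 0.18 ± 0.07 (adjusted p = 0.184).

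The lower proteasome scores at 12 h were tested against 3 technical sources, chosen after the shift itself had been seen and before the results of these tests were. Noise of the untreated gradients stays open. It does not enter 12 h against the mean of 3 h and 6 h, where 20 of 28 genes lay below 0 (median -0.06, camera p = 0.0137; exact permutation p = 0.0476 over 84 splits), but the call against untreated cells was lost without untreated replicate 1 or 2 (adjusted p = 0.199 and 0.159) and with an estimated correlation (0.84). Weak fraction arrays stay open too, although the camera call held without them (adjusted p = 0.00367). Of the untreated and 12 h arrays in the score, this left out only fraction 6 of untreated replicate 2. In untreated cells proteasome genes were lower in fraction 6 (0.415 ± 0.182) than in the later fractions. The score of that gradient then rests on other fractions than the rest, so the test cannot decide. Dependence on a single gradient stays open, with an adjusted p of up to 0.18 without 1 gradient of 12 h. Of 10 splits of the 6 gradients, 6 called at least the 1 list of the real one, with up to 2 lists, so this call may not reflect UVC.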
